A study of Oryza sativa with 20 samples.

How the data were processed

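RNA sequencing was carried out on root tissue of 5 rice cultivars, Azucena, Bala, Moddai Karuppan, Niyan Wee and Sarali, with 4 libraries per cultivar and 20 libraries in all. Libraries were prepared from total RNA with a stranded kit that includes removal of ribosomal RNA, per the labels' protocols, although another label names polyadenylated RNA as the molecule. HISAT2 (version not given), edgeR 3.36.0 and the genome build IRGSP-1.0 are named in the submitters' processing notes, with no role or order stated there. The counting tool, the annotation version and the treatment of reads that match several genes are not given in the sources used here.

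The deposited table holds expected counts per gene and library, as read counts of which 7.58% of the values are not whole, per the file headers and the values. The authors gave each gene a gene symbol of the LOC type and, for 19010 of the 21237 gene rows, an MSU7 locus identifier. Another 2 rows named no gene, held no counts and were left out. Every gene row reached at least 1 CPM (a count scaled to the library total) in at least 3 libraries, so the table had already been filtered on low counts. Gene names and biotypes were taken from a reference table of assembly ASM3414082v1, to which 20839 rows were matched by gene number or symbol. That assembly is not the build named in the notes, so no coordinates are given, and the table served only for names, biotypes and the order of genes. Because reads shared between near-identical genes can have been divided or lost in counting, values of single members of such families (histone H2B, the neighbouring nicotianamine synthase genes NAS1 and NAS2, expansins, the neighbouring aquaporins PIP2-1 and PIP2-5) are uncertain.

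The design called for raw counts. Since the deposited values were partly fractional, they were rounded to whole numbers before testing. Genes were filtered with filterByExpr by cultivar at a minimum count of 10, which removed 12 genes and left 21225. Libraries were scaled with the TMM method and tested with edgeR 4.0.16 (estimateDisp, glmQLFit, glmQLFTest) in R 4.3.3, in a single model of all 20 libraries with 1 mean per cultivar and no other term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. CPM values in the text are TMM-scaled, given as mean ± SD over libraries, and log2 fold changes come from the model. The comparisons were an F test among the 5 cultivars, an F test among the 3 Sri Lankan cultivars, Azucena against the mean of the 4 others, the Sri Lankan mean against Bala, each Sri Lankan cultivar against the mean of the other two, and all 10 pairs.

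Of the 33 listed aquaporins 19 were found by locus identifier. PIP2-5 and NIP3-1, whose listed identifiers have no entry in the table, were found by name and chromosome only after values had been seen, so the counts of 19 were kept and those of 21 are given beside them.

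The cultivar comparisons, their tests, most alternatives, 7 lists of genes and the rule for naming genes were chosen before the data were examined. The 7 lists held aquaporins and genes of nutrient uptake, iron and metal acquisition, drought and abscisic acid, low oxygen, diterpenoid phytoalexins and root development. Lists that were to be built from product descriptions were not run, because no product descriptions were given. In their place, 7 lists were built from gene name patterns after the counts of changed genes and the aquaporin values had been seen: the Casparian strip family, expansins, cell division (MCM, cyclin, PCNA and histone H2B genes), heat shock proteins, ribosomal proteins, a leaf marker list and class III peroxidases. The 10 lists with at least 5 measured genes were tested in 5 comparisons with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM values with a prior count of 2, adjusted over the 50 tests, and again with an estimated correlation and with fry. After that, 53 families of genes that share a name prefix were tested in the same way in 2 comparisons.

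Genes were named by the rule as follows. All measured aquaporins were eligible. For Azucena against the others and for the Sri Lankan mean against Bala, named genes that passed and whose libraries did not overlap between the sides were ranked by fold change (the 6 highest and 6 lowest with a mean of at least 5 CPM in the higher side) and by p (the 4 smallest in each direction with at least 10 CPM in every cultivar). For each Sri Lankan cultivar the 3 highest and 3 lowest fold changes were taken. From each other list, up to 4 members with the smallest p were eligible. Further list members are named where a count was small or a value stands out, and these were chosen after their values were seen. The result of 1 gene of the lists is not reported here.

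Total counts per library lay between 23444550 and 31996643. Counts in 23 ribosomal RNA genes were kept in the table as designed. Without them, 3813615 to 28063068 counts per library remained. Nothing in the labels says that libraries of a cultivar came from separate plants, so the p-values measure the spread between these libraries, which may be technical. Within each cultivar every pair of libraries differed by far more than sampling noise (chi-square per degree of freedom 14.2 to 120.5), so all were counted as separate.

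The labels give each library a batch replicate number from 1 to 4 that is shared across cultivars, which pairs libraries by label. Deviations from the cultivar means correlated with a mean r of 0.03 over the 40 pairs with the same number and −0.01 over the 120 pairs with different numbers, a correlation across genes, which are not independent replicates. Among pairs that share number 1 the mean was 0.17. A fit with the replicate number as a block was an alternative.

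Alternatives were RLE scaling, DESeq2 1.42.0, the legacy quasi-likelihood fit, no filter, a filter of at least 1 CPM in at least 4 libraries, the replicate block, the pool as a covariate, each of the 2 pools alone (a pool, P1 or P2, is given for each library per the file headers, which do not say what was pooled), each pair fitted on its own 8 libraries, and each library left out in turn. After the data had been seen, fits without the ribosomal RNA genes, with the log odds of the ribosomal RNA share as a covariate, with the newer quasi-likelihood method, on counts thinned to the smallest non-ribosomal total, and without the 2 libraries with the fewest non-ribosomal counts (Bala replicates 3 and 4) were added. Later still came fits without Niyan Wee replicates 2 and 3 and Sarali replicate 3, which several other splits of the libraries had put together, and the 2 aquaporins matched by name.

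The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. The counts were drawn independently per gene and library, with 1 mean per gene apart from these changes. They held no structure among libraries or genes, so the false calls need not hold for the real libraries. For Azucena against the others (21210 genes) the procedure recovered 50 of the 2-fold and 89 of the 4-fold changes with 6 false calls. For the Sri Lankan mean against Bala (21212 genes) it recovered 41 and 92 with 10 false calls, and for Moddai Karuppan against the other two Sri Lankan cultivars (21205 genes) 47 and 90 with 6 false calls. For the F test among the 5 cultivars with changes placed in Niyan Wee (21200 genes) it recovered 32 and 84 with 3 false calls.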

Results

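Root transcriptomes were compared among 5 rice cultivars. Moddai Karuppan, Niyan Wee and Sarali were taken as the Sri Lankan Indica II cultivars that the series title speaks of without listing them, Bala is an upland indica cultivar and Azucena an upland tropical japonica cultivar. Each was represented by 4 libraries. The series is about aquaporins, the membrane channels for water and small neutral solutes, and the comparisons asked how their expression and that of other genes differed among the roots.

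Ribosomal RNA took the largest mean share of the counts in Bala. It made up 49.2% ± 9.33 in Azucena, 73.3% ± 9.12 in Bala, 42.0% ± 7.75 in Moddai Karuppan, 31.0% ± 23.5 in Niyan Wee and 52.9% ± 15.4 in Sarali (mean ± SD, n = 4 each). The lowest library was Niyan Wee replicate 1 at 4.07% and the highest Bala replicate 4 at 84.6%. Bala exceeded the Sri Lankan libraries by 31.3 percentage points (exact permutation test, two-sided, p = 0.00495, 1820 arrangements), whereas Azucena differed from the other libraries by −0.56 points (exact p = 0.958, 4845 arrangements). Bala libraries held the fewest counts in other genes, 6918016 ± 2936360 against 13614844 ± 2432928 in Azucena and 19387729 ± 7666206 in Niyan Wee (mean ± SD, n = 4 each).

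**Figure D1:**
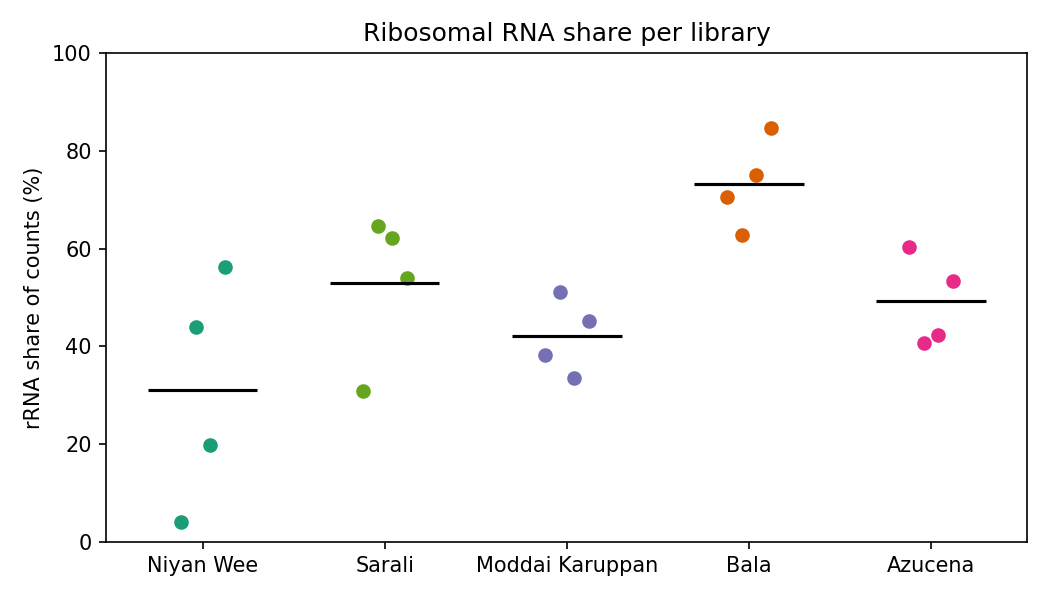
Share of counts in ribosomal RNA genes (%) in each of the 20 libraries, by cultivar, with a line at each cultivar mean. The 4 Bala libraries lie between 62.8% and 84.6%, while the Niyan Wee libraries run from 4.07% to 56.2%.

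Cultivar separated the libraries. The first principal component of log2 CPM (31.7% of the variance) set Azucena apart from the rest, the second (20.0%) set Bala apart, and the 3 Sri Lankan cultivars lay close together on both. The third (9.09%) set Niyan Wee apart from Sarali and Moddai Karuppan, with Azucena replicate 3 near it. The fourth (7.59%) set Moddai Karuppan apart from Sarali. Of 21225 genes tested, 6032 (28.4%) differed among the 5 cultivars and 854 (4.02%) among the 3 Sri Lankan cultivars (edgeR quasi-likelihood F tests, adjusted p below 0.05). The latter was 500 without Niyan Wee replicates 2 and 3 and Sarali replicate 3, which other splits of the libraries put together.

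**Figure D2:**
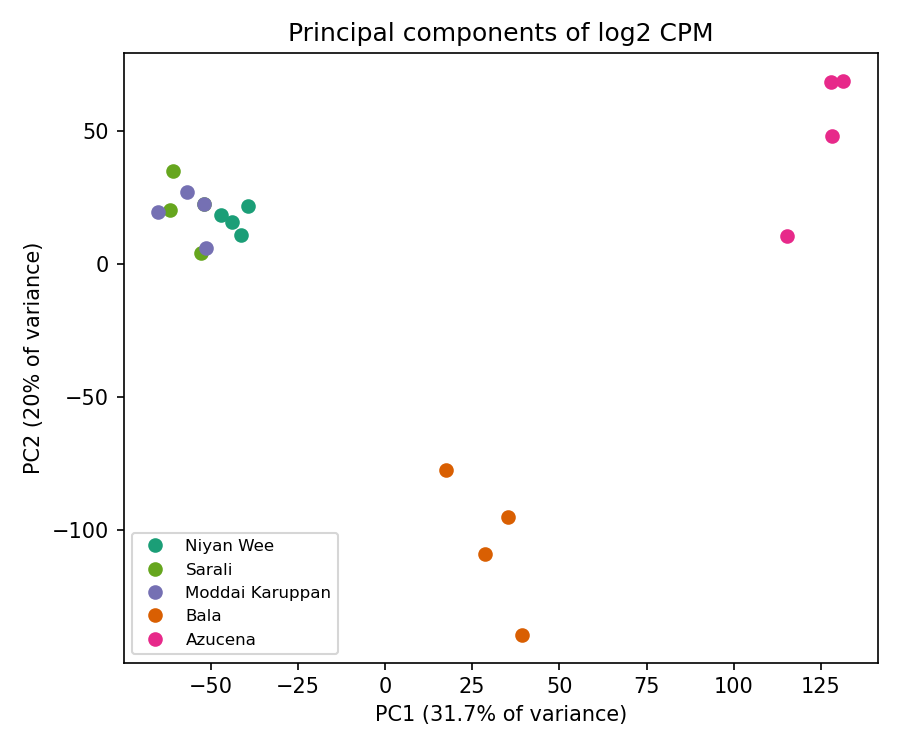
Libraries on the first and second principal components of log2 CPM (31.7% and 20.0% of the variance). Each point is a library, coloured by cultivar; Azucena stands at the right, Bala at the bottom and the Sri Lankan libraries together at the left.

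Averaged over all libraries, the highest aquaporins were the tonoplast intrinsic proteins TIP2-2 and TIP1-1 and the plasma membrane intrinsic protein PIP2-1, with 663, 600 and 380 CPM. The order was not the same in each cultivar. In Azucena TIP1-1 stood above TIP2-2 in each of the 4 libraries (means of 420 and 381 CPM). In Niyan Wee the means were 449 for TIP1-1 and 412 for TIP2-2, but 208 and 242 without replicate 4. PIP1-3 (449) and PIP1-1 (419) lay near PIP2-1 (416) in Bala, as did PIP1-3 (283) near PIP2-1 (281) in Niyan Wee. Each of these orders in Bala and Niyan Wee turned when 1 library was left out, while that in Azucena did not. The clearest difference among cultivars was in TIP1-2 (LOC_Os01g74450), which stood at 10.7 ± 4.29 CPM in Azucena, against 36.0 ± 15.0 in Bala, 27.8 ± 10.6 in Moddai Karuppan, 29.1 ± 11.9 in Niyan Wee and 49.1 ± 20.5 in Sarali (mean ± SD, n = 4 each). NIP2-1 (LOC_Os02g51110), the silicon influx channel also known as Lsi1, was highest in Bala at 404 ± 197 CPM and lowest in Moddai Karuppan at 92.2 ± 38.0, with 178 ± 141 in Azucena, 206 ± 88.6 in Niyan Wee and 172 ± 74.9 in Sarali. PIP2-5 (LOC_Os07g26660) stood at 38.3 ± 23.9 CPM in Bala, against 4.98 ± 1.89 in Azucena, 8.28 ± 5.64 in Moddai Karuppan, 12.4 ± 7.13 in Niyan Wee and 12.3 ± 11.2 in Sarali. The most abundant channels did not pass the test. TIP2-2, for example, stood at 1010 ± 329 CPM in Sarali and 381 ± 271 in Azucena (adjusted p = 0.172), and PIP2-1 between 281 ± 179 in Niyan Wee and 419 ± 48.0 in Sarali (adjusted p = 0.527).

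Of 33 aquaporins in the list, 19 were matched by locus identifier. PIP2-5 and NIP3-1 were matched by name only after the other values had been seen and are counted separately, and the other 12 were not analysed here. TIP1-2 (adjusted p = 0.00841) and NIP2-1 (adjusted p = 0.0258) differed among the 5 cultivars over all genes tested, and adjusted over the list alone only TIP1-2 passed (0.0255, against 0.0555 for NIP2-1). At an unadjusted p below 0.05 there were 5. The share of aquaporins that passed was not shown to differ from that of the other genes (Fisher's exact test, two-sided, p = 0.124). The spread within cultivars was wide, with a median coefficient of variation of 38.5% over the 16 aquaporins of at least 10 CPM against 16% over 9445 genes of that level. The NIP2-1 call ended with the ribosomal RNA share as a covariate (adjusted p = 0.0876), without Bala replicates 3 and 4 (0.131), and without Moddai Karuppan replicate 1 (0.0504), 3 (0.0595) or 4 (0.0602) or Bala replicate 1 (0.0788) or 4 (0.104). With the replicate block it ended too (0.0646) and PIP1-2 passed (0.0231, against 0.0908 without it). Without Niyan Wee replicate 4 the number that passed was 8, it was 1 when Moddai Karuppan replicate 1, 3 or 4 or Bala replicate 1 or 4 was left out, and DESeq2 gave 4. Of the 2 matched by name, PIP2-5 differed among the 5 cultivars (adjusted p = 0.013, 0.0251 over the list alone) and NIP3-1 did not pass (0.318), which makes 3 of 21, also over the list alone, and 6 at an unadjusted p below 0.05 (Fisher's exact test, two-sided, p = 0.225). The PIP2-5 call ended without Bala replicate 1 (0.0663) or 4 (0.0543), with the ribosomal RNA share as a covariate (0.0554) and without Bala replicates 3 and 4 (0.0664).

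Between single pairs of cultivars, 7 of 190 tests of the 19 aquaporins passed, in 4 of them, and 9 of 210 with the 2 matched by name. PIP2-5 was lower in Azucena than in Bala (log2 fold change −2.93, adjusted p = 0.00611) and higher in Bala than in Moddai Karuppan (2.21, 0.0313). The latter call ended without Bala replicate 1 (0.0906) or 4 (0.0893) or Moddai Karuppan replicate 1 (0.0918), 3 (0.0897) or 4 (0.0762), with the ribosomal RNA share as a covariate (0.113) and without Bala replicates 3 and 4 (0.114). TIP1-2 was lower in Azucena than in Sarali (log2 fold change −2.20, adjusted p = 0.000974), Bala (−1.75, 0.00774), Niyan Wee (−1.45, 0.0238) and Moddai Karuppan (−1.38, 0.0243), and lower than the mean of the 4 (−1.69 ± 0.366 SE, adjusted p = 0.00209). NIP2-1 was higher in Bala than in Moddai Karuppan (2.13, adjusted p = 0.00732, 0.0512 without Bala replicates 3 and 4). The other tests that passed were PIP2-2, lower in Azucena than in Bala (−1.25, adjusted p = 0.0448, 0.0578 with the replicate block), and TIP4-1, higher in Azucena than in Moddai Karuppan (0.65, adjusted p = 0.0398). The PIP2-2 call ended with the covariate (0.132), without Bala replicates 3 and 4 (0.199), with the pool as a covariate (0.0511) and without any of 10 single libraries: Niyan Wee replicate 1 (0.0502), Moddai Karuppan replicate 1 (0.0535), 3 (0.0507) or 4 (0.0527), Bala replicate 1 (0.0909) or 4 (0.179) and Azucena replicate 1 (0.0778), 2 (0.116), 3 (0.0612) or 4 (0.0914). The TIP4-1 call ended with the ribosomal RNA share as a covariate (0.0505), on thinned counts (0.0687) and without Moddai Karuppan replicate 2 (0.0703), 3 (0.102) or 4 (0.0895) or Azucena replicate 3 (0.201) or 4 (0.0676). The TIP1-2 call against Bala ended with the ribosomal RNA share as a covariate (0.0505) and without Bala replicates 3 and 4 (0.105). That against Moddai Karuppan ended without Moddai Karuppan replicate 2 (0.0755) or 4 (0.0624) or Azucena replicate 2 (0.0701) or 4 (0.0738). That against Niyan Wee ended on thinned counts (0.0532) and without Niyan Wee replicate 3 (0.0629) or 4 (0.0773) or Azucena replicate 2 (0.082) or 4 (0.0813).

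Among the 3 Sri Lankan cultivars 0 of 19 aquaporins differed by edgeR, and 0 of 21 with those matched by name. There was 1 at an unadjusted p below 0.05, 0 by DESeq2, and at most 1 that passed under any alternative.

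**Figure D3:**
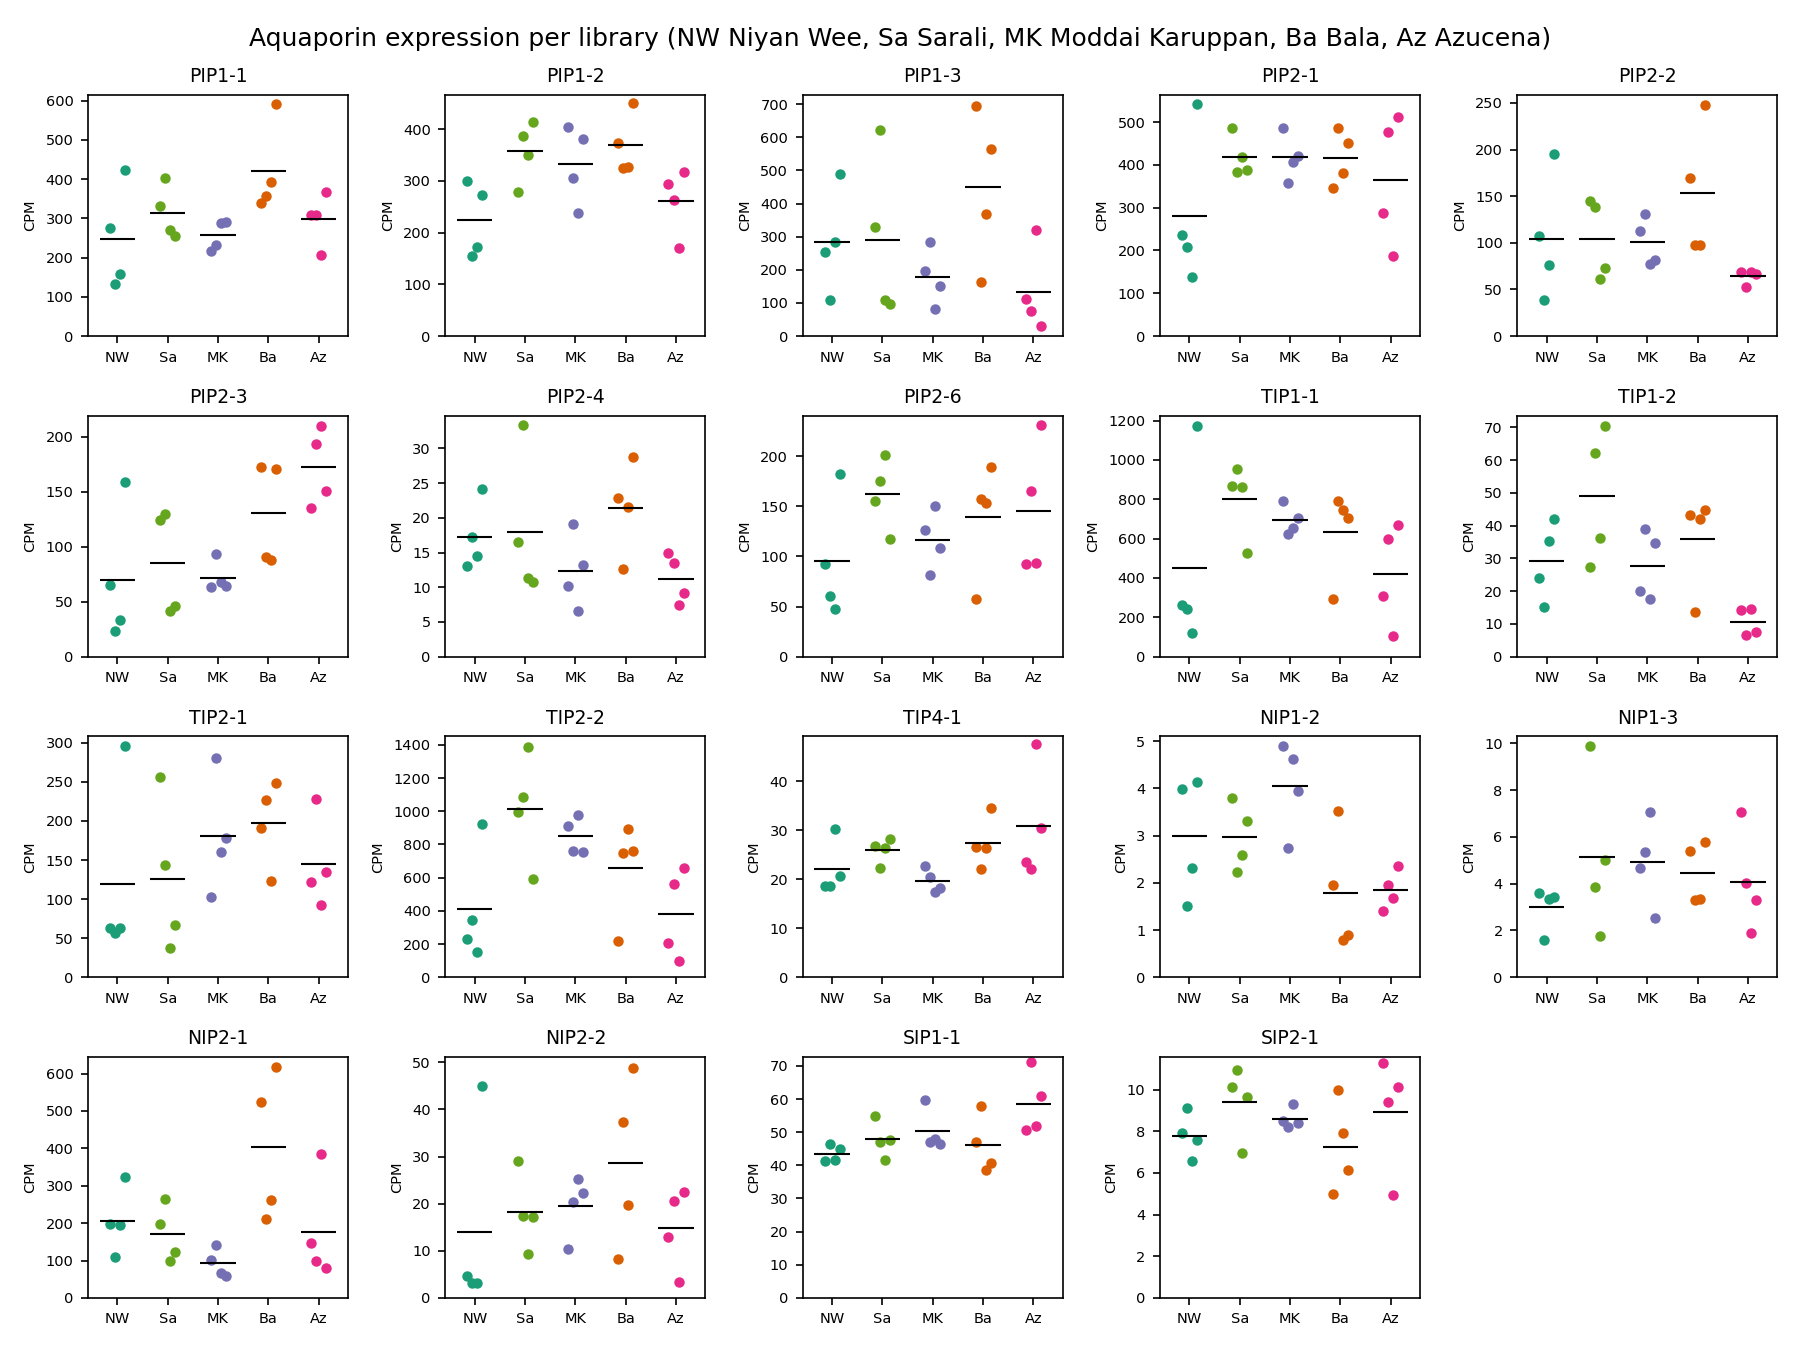
Expression (TMM-scaled CPM, linear axis from 0) of the 19 aquaporins matched by identifier in each library, by cultivar, with a line at each mean. The 4 Azucena points of TIP1-2 average 10.7 CPM, while in Niyan Wee 1 library stands far above the other three in TIP1-1 at 1170 CPM.

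Azucena roots differed from the mean of the 4 other cultivars in 4277 genes, of which 2542 were higher and 1735 lower (59.4% higher against 54.5% by DESeq2). Of the called genes with a mean of at least 10 CPM, 44.5% were higher. The 3 highest named genes averaged under 1 CPM elsewhere. The expansin EXPA32, a cell wall loosening protein, stood at 11.0 ± 3.47 CPM in Azucena (n = 4) and 0.0493 ± 0.126 in the others (n = 16). The small heat shock protein Hsp18.0 stood at 23.3 ± 5.74 against 0.104 ± 0.125, and the germin-like protein GER3 at 14.5 ± 8.11 against 0.66 ± 0.793. The lowest were BURP16, a BURP domain protein, at 0.818 ± 0.899 against 38.4 ± 19.1 CPM, and CLPB1, the chaperone HSP101, at 0.627 ± 0.749 against 9.48 ± 2.73. Without Azucena replicate 3 their log2 fold changes went from −5.46 to −6.6 and from −3.87 to −5.23.

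Other genes higher in Azucena were SDH7 (16.6-fold, adjusted p = 2.18e-13), CCS1 (10.1-fold, 1.24e-09), the ascorbate peroxidase APx05 (7.77-fold, 0.000817), the succinate dehydrogenase subunit SDH3-2 (3.57-fold, 1.08e-10) and the superoxide dismutase RMSOD1 (2.72-fold, 5.45e-06). DOHH-A and SPP30-like were 1.61-fold and 1.33-fold higher. Genes lower in Azucena included the potassium channel AKT1, at 21.1 ± 11.3 against 103 ± 42.5 CPM (log2 fold change −2.20 ± 0.357 SE, adjusted p = 0.000119), and the ubiquitin ligase XB3, at 38.1 ± 6.09 against 144 ± 21.5 (−1.91 ± 0.135, 2.87e-09). BADH2, the betaine aldehyde dehydrogenase known from grain fragrance, stood at 18.8 ± 6.35 against 68.9 ± 8.25 CPM (−1.87 ± 0.156, 2.44e-08), and the auxin response repressor IAA3 at 34.3 ± 10.4 against 126 ± 20.2 (−1.87 ± 0.167, 6.23e-08). Clot, the MADS-box gene MADS57 and the zinc finger gene C3H27 had log2 fold changes of −2.07, −2.04 and −1.78. Calls of all genes named in this and the preceding paragraph held when any single library was left out.

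Of 31 expansins measured, 15 were higher in Azucena, 0 were lower and 16 did not pass, with 16 higher adjusted over the list alone. None was lower by DESeq2 or at an unadjusted p below 0.05. Among those higher, EXPB4, EXPB11, EXPB16, EXPA1 and EXPA4 were also lower in the Sri Lankan mean than in Bala. The mean of the 4 others hides their higher level in Bala, so a difference between Azucena and Bala is not shown for them. Only EXPA32, EXPB17 (log2 fold change 1.28, adjusted p = 0.00357) and EXPA10 (0.43, 0.00573) kept their calls without any single library. The list passed with camera (adjusted p = 0.00482), and adjusted p = 0.423 with an estimated correlation. Without Azucena replicate 4, 6 expansins were higher, and 9 and 3 in pools P1 and P2 alone.

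**Figure D4:**
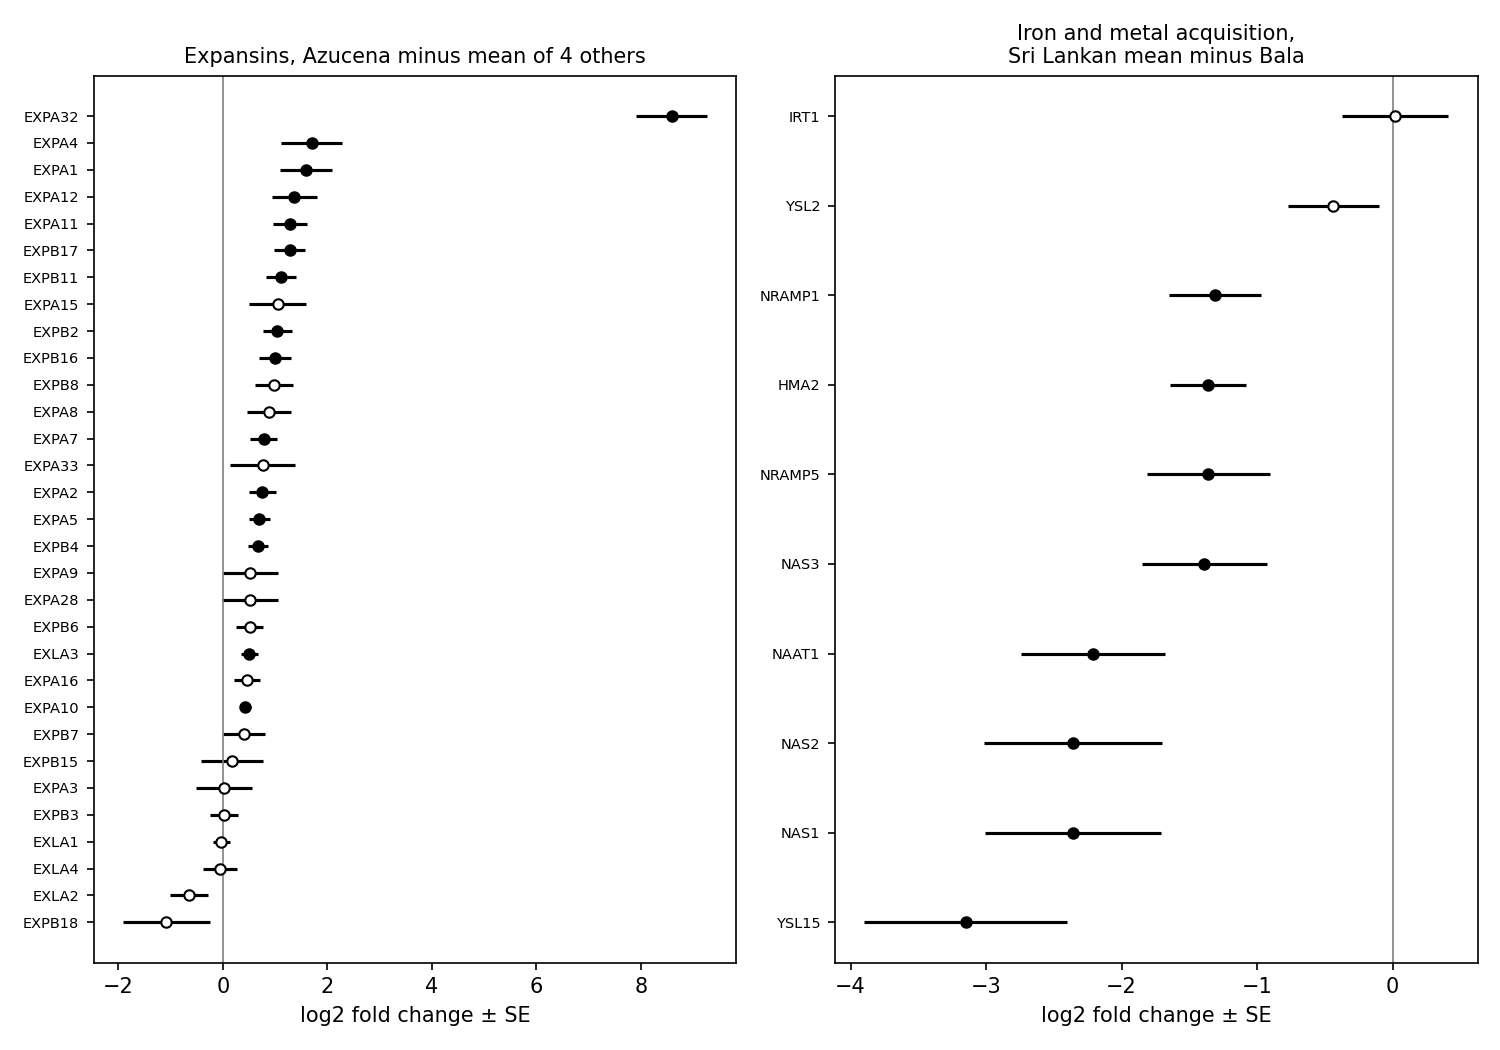
Log2 fold changes with their standard errors of the 31 expansins (Azucena minus the mean of the 4 others) and the 10 measured genes of iron and metal acquisition (Sri Lankan mean minus Bala). Filled points passed at an adjusted p below 0.05; 15 expansins lie above 0 and 8 iron genes below it.

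Of 37 cell division genes, 7 rose in Azucena and 3 fell. The cyclin CYCD5-3 rose (13.6 ± 1.3 CPM, 1.56 on the log2 scale, adjusted p = 4.09e-06), as did H2B.4 (0.71, 0.000299) and H2B.2 (0.59, 0.00426), while H2B.7 (−0.96, 0.000594), H2B.10 (−0.91, 0.00125) and CYCA1-4 (−0.59, 0.00283) fell. The number that rose was 4 without Azucena replicate 2 or 4, 3 without Azucena replicate 3, where 5 fell, 11 without Niyan Wee replicate 2, and 16 without Niyan Wee replicates 2 and 3 and Sarali replicate 3, where 4 fell. Adjusted over the list alone, 11 rose and 5 fell. Among heat shock proteins 2 of 15 rose and 1 fell, the same over the list alone (HSP18.0 and HSP17.9B rose, hsp101 fell; HSP17.9B ended without Azucena replicate 1, adjusted p = 0.074). In the Casparian strip family, named for the barrier of the endodermis, 3 of 23 rose and 1 fell, and 2 and 1 adjusted over the list alone. CASPL2C1 was lower (−1.17, adjusted p = 0.00464). CASP1 (1.56, 0.018; 0.92 without Azucena replicate 3), CASPL1D1 (1.78, 0.0232) and CASPL4B1 (0.82, 0.049, 0.0673 with the replicate block) were higher, but CASP1 ended without Azucena replicate 3 (0.216), CASPL1D1 without Azucena replicate 1 (0.131) or 3 (0.0934), and CASPL4B1 without any of 14 libraries (0.144 without Azucena replicate 1). CASPL1D1 (0.0584) and CASPL4B1 (0.0833) also ended on thinned counts, the latter with the pool as a covariate (0.0558) and RLE scaling (0.0501), and both (0.0561 and 0.0558) without Niyan Wee replicates 2 and 3 and Sarali replicate 3, where 1 of the family rose and 3 fell. In the Sri Lankan mean against Bala, CASPL1D1 and CASP1 were lower (−3.63 and −1.54) and H2B.10 was higher (1.1). For these genes the mean of the 4 others hides the level in Bala, so a difference between Azucena and Bala is not shown.

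Single members of the lists of nutrient uptake, iron, drought and phytoalexin genes passed in Azucena, where 20.2% of all genes tested did. Of 11 nutrient uptake genes the phosphate transporter PT6 rose (2.13, adjusted p = 0.00712) and AKT1 fell, also adjusted over the list alone. Of 10 iron and metal genes 1 rose, also over the list alone: NAS3, a nicotianamine synthase (1.74, adjusted p = 0.00484, 0.0566 without Azucena replicate 3). NAS3 was also lower in the Sri Lankan mean than in Bala (−1.39, edgeR adjusted p = 0.0423), so a difference between Azucena and Bala is not shown for it. Of 16 drought genes NAC5 rose (0.80, adjusted p = 0.0344), with 0 over the list alone, and that call ended with the replicate block (0.0729) and without Azucena replicate 3 (0.466) or Niyan Wee replicate 1 (0.0521). Of 3 diterpenoid phytoalexin genes CPS4 rose (2.53, adjusted p = 0.0148; 3.24 without Sarali replicate 1), also over the list alone, but not without Azucena replicate 1 (1.44, 0.245). Single pools aside, the CPS4 call also ended under 1 other alternative. Of 7 low oxygen genes, 4 root development genes, 31 ribosomal protein genes, 2 leaf markers and 2 class III peroxidases, 0 passed by edgeR, over all genes or over the list alone. At an unadjusted p below 0.05 there were 1, 0, 6, 0 and 0 of these, and by DESeq2 1, 0, 1, 0 and 0. Of the ribosomal protein genes, however, 16 rose without Niyan Wee replicates 2 and 3 and Sarali replicate 3, 5 without Niyan Wee replicate 2 alone and 3 with the ribosomal RNA share as a covariate. NAC5 (0.0579) ended without those 3 libraries. Among aquaporins TIP1-2 fell and SIP1-1 rose (0.32, adjusted p = 0.0467), the latter ending without any of 14 libraries (0.249 without Azucena replicate 2) without those 3 (0.0705) and without Bala replicates 3 and 4 (0.0858), and adjusted over the list alone only TIP1-2 passed. PIP2-5 did not pass here by edgeR (−1.57, adjusted p = 0.0605), though it did by DESeq2 (0.00835).

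The Sri Lankan mean differed from Bala in 3816 genes, 1658 higher and 2158 lower (43.4% higher against 47.4% by DESeq2). The cellulose synthase-like gene CslE6 stood at 23.5 ± 8.03 CPM in the Sri Lankan libraries (n = 12) and 0.173 ± 0.267 in Bala (n = 4), and the MADS-box gene MADS56 at 20.1 ± 5.14 against 0.433 ± 0.636. Lower in the Sri Lankan cultivars were BURP02, a BURP domain gene, at 0.973 ± 0.674 against 66.8 ± 49.9 CPM, and OrysaZxb at 0.742 ± 0.395 against 26.5 ± 9.8. The chitinase Chia2a stood at 1.33 ± 0.761 against 11.2 ± 5.28 and the sodium transporter HKT1;3 at 0.847 ± 0.728 against 6.86 ± 2.05.

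Among the genes with the smallest p-values, the Dicer-like gene DCL2a was higher in the Sri Lankan cultivars (2.21 ± 0.173 SE on the log2 scale, adjusted p = 1.81e-08) and SGS3 was lower (−1.03 ± 0.128, 9.74e-06). Further genes that were higher were MADS16 (2.27, and 2.92 without Bala replicate 1), IRL1 (2.26), wsl3 (1.94), C3H49 (1.72), MADS47 (1.69) and the plastid phosphoenolpyruvate translocator PPT2 (0.93). Further genes that were lower were CBP1 (−3.56), EME1 (−2.76), GLU3, an endoglucanase (−1.38), SDH3-2 (−1.24) and the protein kinase CIPK24 (−1.03). Each of the genes named so far for Bala kept its call without any single library. The ribosomal RNA share was 31.3 points higher in Bala. The number of genes that differed was 1607 with that share as a covariate, 2332 without Bala replicate 4 and 1484 without Bala replicates 3 and 4, which had the fewest non-ribosomal counts.

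Of 10 measured genes of iron and metal acquisition, 8 were lower in the Sri Lankan cultivars than in Bala, 0 were higher and 2 did not pass, also adjusted over the list alone, with 0 higher by DESeq2 or at an unadjusted p below 0.05. The iron-phytosiderophore transporter YSL15 stood at 6.60 ± 4.56 CPM in Bala against 0.513 ± 0.534 to 1.16 ± 0.956 in the 3 others (log2 fold change −3.15 ± 0.75 SE, adjusted p = 0.00623). NAAT1, an enzyme of phytosiderophore synthesis, stood at 14.2 ± 7.18 in Bala against 2.18 ± 2.14 to 4.10 ± 2.57 (−2.21 ± 0.53, 0.00659), and the metal pump HMA2 at 79.1 ± 38.7 against 26.5 ± 5.84 to 35.1 ± 16.5 (−1.36 ± 0.28, 0.00202). NAS1, NAS2, NAS3, NRAMP1 and NRAMP5 made up the rest. NAS1 and NAS2 ended without Bala replicate 1 (0.0603 and 0.078) or 4 (0.0755 and 0.0682) and NRAMP1 without Bala replicate 4 (0.249), while NAS3 ended without any of 9 libraries (0.175 without Bala replicate 4) and NRAMP5 without any of 12 (0.183 without Bala replicate 4), with the replicate block (0.0762), with the pool as a covariate (0.0529) and without Niyan Wee replicates 2 and 3 and Sarali replicate 3 (0.116). The list passed with camera (adjusted p = 0.00415), and adjusted p = 0.795 with an estimated correlation. The ribosomal RNA share was 31.3 points higher in Bala, and the number lower was 1 with that share as a covariate, 0 by edgeR without Bala replicates 3 and 4 (5 at an unadjusted p below 0.05), 2 in pool P1 alone, 3 without Bala replicate 4 and 4 without Bala replicate 1.

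Of 31 expansins, 10 were lower in the Sri Lankan cultivars than in Bala and 0 higher by edgeR, with 13 falling adjusted over the list alone, and 0 rose by DESeq2 while 1 did at an unadjusted p below 0.05. EXPB4 stood at 38.5 ± 11.3 CPM in Bala against 12.1 ± 1.89 to 16.1 ± 2.19 (−1.39, adjusted p = 3.44e-05), and EXPB11 at 11.1 ± 7.62 against 2.73 ± 0.513 to 5.92 ± 1.69 (−1.60, 0.00102, 0.0781 with the ribosomal share as a covariate). The list passed with camera (adjusted p = 0.00153), and adjusted p = 0.423 with an estimated correlation. Beside the 31.3 points more ribosomal RNA in Bala, the number that fell was 4 with that covariate, 5 without Bala replicate 4, 6 without Bala replicate 1, without Bala replicates 3 and 4 or in pool P1 alone, and 3 in pool P2 alone.

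Of 11 nutrient uptake genes, 2 were higher and 3 lower in the Sri Lankan cultivars, and 3 and 3 adjusted over the list alone. The potassium and sodium transporter HKT2-1 was higher, at 2.68 ± 0.838 to 3.00 ± 1.43 CPM against 0.0649 ± 0.13 in Bala (adjusted p = 0.000464). The Bala value rests on 4 counts in replicate 1 and 0 in the other three, so no fold is given. The silicon efflux transporter LSI2 was lower, at 50.2 ± 19.4 to 123 ± 67.3 against 331 ± 196 (−2.05, adjusted p = 0.00424, 0.119 with the ribosomal share as a covariate, 0.0826 without Bala replicates 3 and 4), as was its partner NIP2-1 among the aquaporins (−1.44 ± 0.366 SE, adjusted p = 0.00947, 0.166 with the covariate, 0.123 without Bala replicates 3 and 4 and 0.0763 without Bala replicate 4). The aquaporin PIP2-5 was lower too (−1.82 ± 0.484, adjusted p = 0.0127, 0.167 with the covariate, 0.096 without Bala replicates 3 and 4, 0.0811 without Bala replicate 1 and 0.0691 without Bala replicate 4), and no other aquaporin passed in this comparison. AKT1 (1.09, adjusted p = 0.0301), HAK1 (−1.04, 0.0284) and the nitrate transport partner NAR2.1 (−2.02, 0.0223) also passed. All 3 ended with the covariate (0.271, 0.207 and 0.405) and without Bala replicates 3 and 4 (0.395, 0.477 and 0.151). They ended too without Bala replicate 4 (0.123, 0.192 and 0.138), AKT1 and NAR2.1 without Bala replicate 1 (0.108 and 0.0837), and AKT1 and HAK1 without Bala replicate 3 (0.098 and 0.0594). HAK1 (0.0801) and NAR2.1 (0.0545) ended without Niyan Wee replicates 2 and 3 and Sarali replicate 3, where 1 gene of the list was lower.

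Single members moved in the other lists. The sucrose synthase SUS2 fell among 7 low oxygen genes (−0.83, adjusted p = 0.000113), SALT, a salt-induced lectin, rose among 16 drought genes (2.12, 0.00699, with 1150 ± 379 CPM in Moddai Karuppan but 12.2 ± 6.46 in Niyan Wee and 17.2 ± 3.25 in Sarali against 14.3 ± 2.91 in Bala, and 0.122 without Bala replicates 3 and 4), and SHR1 fell among 4 root development genes (−0.97, 0.0083, 0.0591 without Bala replicate 1, 0.183 without Bala replicates 3 and 4, 0.281 with the ribosomal share as a covariate). In the Casparian strip family 2 of 23 rose, CASPL4B3 (2.16, adjusted p = 0.016, 0.119 without Bala replicates 3 and 4) and CASPL1E1 (1.36, 0.0255), and 2 fell, CASPL1D1 (−3.63, 0.000156; −2.72 without Bala replicate 4) and CASP1 (−1.54, 0.0323, 0.0557 with the replicate block). CASPL1E1 ended without Bala replicate 2 (0.0522), 3 (0.0891) or 4 (0.096), and CASP1 without Bala replicate 1 (0.121) or 4 (0.132), and both with the covariate (0.233 and 0.155) and without Bala replicates 3 and 4 (0.359 and 0.0843). CASP1 ended without Niyan Wee replicates 2 and 3 and Sarali replicate 3 as well (0.0803). Of 37 cell division genes 1 rose (H2B.10, 1.1, 0.000595) and 2 fell, H2B.3 (−1.12, 0.000467) and CYCD5-1 (−1.01, 0.00518, 0.0569 without Bala replicate 4, 0.248 without Bala replicates 3 and 4, 0.0725 with the covariate), and 6 fell without those 3 libraries, as did 10 of 31 ribosomal protein genes, of which 0 fell with all libraries. The peroxidase PRX74 fell (−2.18, adjusted p = 0.00161, 0.0741 with the ribosomal share as a covariate), as did 1 of 15 heat shock proteins, HSP23.2 (−2.68, 0.013, −1.41 and 0.271 without Bala replicate 4, 0.862 without Bala replicates 3 and 4, 0.516 with the covariate). These counts were the same adjusted over the list alone. Of 3 diterpenoid phytoalexin genes and 2 leaf markers 0 passed by edgeR or DESeq2, with 1 and 0 at an unadjusted p below 0.05.

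Among the Sri Lankan cultivars the largest named difference was in the mannose-binding lectin ML, the product of SALT. It stood at 1150 ± 379 CPM in Moddai Karuppan (n = 4) against 14.7 ± 5.44 in the other two (n = 8), a 79.4-fold difference (log2 fold change 6.31 ± 0.503 SE, adjusted p = 8.82e-08), and at 14.3 ± 2.91 in Bala and 90.7 ± 63.7 in Azucena. DGAT1-2, a diacylglycerol acyltransferase of oil synthesis, was also higher in Moddai Karuppan, at 37.9 ± 6.24 against 6.96 ± 1.4 CPM (2.44 ± 0.169, 1.66e-08). AO-1 (−2.03), the potassium transporter HAK18 (−1.61) and SPO11-4 (−1.16) were lower. OC-X was 4.92-fold higher (adjusted p = 0.0259), a call that ended without Moddai Karuppan replicate 1 (0.0888), 2 (0.0615) or 4 (0.0727), Niyan Wee replicate 1 (0.0562), 2 (0.0547) or 3 (0.0514) or Sarali replicate 2 (0.0571), and without Niyan Wee replicates 2 and 3 and Sarali replicate 3 (0.152).

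Moddai Karuppan differed from the mean of the other two in 432 genes (286 higher, 146 lower, 66.2% higher against 56.6% of 673 by DESeq2). Another split of the Sri Lankan libraries gave 899 genes in this comparison, so the count alone does not set the cultivar apart. Drought genes were higher as a list (camera adjusted p = 0.00482, and adjusted p = 0.423 with an estimated correlation), with 1 of 16 past the threshold, SALT, and 2 adjusted over the list alone. That list call ended without Niyan Wee replicates 2 and 3 and Sarali replicate 3 (0.0596). Cell division genes were lower as a list (adjusted p = 1.81e-06, 0.00794 without those 3 libraries, and adjusted p = 0.629 with an estimated correlation), with 1 of 37 past the threshold and 5 over the list alone. That gene was H2B.11 (−0.86, adjusted p = 0.0157), which ended without Moddai Karuppan replicate 1 (0.102), 2 (0.054) or 3 (0.0637) and without those 3 libraries (0.127). SUS2 was the only low oxygen gene that passed, also over the list alone (−0.56, adjusted p = 0.0485). Its call ended without any of 14 libraries (0.216 without Moddai Karuppan replicate 1) and, single pools aside, under 6 other alternatives (0.074 with the replicate block).

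Niyan Wee differed from the other two in 656 genes (356 higher, 300 lower, 54.3% higher against 49% of 1254 by DESeq2). Another split of the Sri Lankan libraries gave 604 genes, close to that count. Cell division genes were higher as a list (camera adjusted p = 1.35e-07, and adjusted p = 0.521 with an estimated correlation), with H2B.9 alone of 37 past the threshold, at 37.4 ± 10.1 against 22.5 ± 4.37 CPM (0.74 ± 0.151, adjusted p = 0.00755), and 17 over the list alone. The libraries did not agree, with median deviations of these genes from the cultivar mean of 0.381 in replicate 2, 0.0981 in replicate 3, −0.264 in replicate 1 and −0.266 in replicate 4 on the log2 scale. The list had an adjusted p of 0.0482 without replicates 2 and 3 and of 0.00794 without these and Sarali replicate 3. CslA1, a cellulose synthase-like gene, was higher (50.5 ± 5.14 against 32 ± 5.62 CPM, 0.66), and so was PCF2, a transcription factor of proliferating cells (0.64, adjusted p = 0.0116, 0.0545 with the ribosomal share as a covariate). HAL3 was lower (11.4 ± 3.29 against 21.1 ± 2.52, −0.89). IVD (−0.97, adjusted p = 0.0269, 0.12 with that covariate) was lower too, and ended without Niyan Wee replicate 2 (0.0699) or 3 (0.117) or Moddai Karuppan replicate 3 (0.0501). KRP3, an inhibitor of cyclin-dependent kinases, lay near the threshold (−1, adjusted p = 0.0487). Its call ended without any of 14 libraries (0.156 without Niyan Wee replicate 3), with the replicate block (0.06), on thinned counts (0.139) and with a filter of at least 1 CPM in at least 4 libraries (0.0502). SALT was below the mean of the other two (−3.53, adjusted p = 0.000805), which the level in Moddai Karuppan sets. Without Niyan Wee replicate 3 the number of genes that differed was 371. It was 289 without Niyan Wee replicates 2 and 3 and Sarali replicate 3, and there the calls of H2B.9 (0.219), CslA1 (0.131), PCF2 (0.159), IVD (0.38), KRP3 (0.246) and SALT (0.0507) ended.

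Sarali differed from the other two in 483 genes (258 higher, 225 lower, 53.4% higher against 44.5% of 901 by DESeq2). Another split of the Sri Lankan libraries gave 631 genes, so this count alone does not set Sarali apart either. The argonaute gene AGO4b was higher, at 72.6 ± 14.9 against 39.3 ± 5.34 CPM (0.89 ± 0.139, adjusted p = 0.000698), and PPDKB, a pyruvate phosphate dikinase, was lower, at 27.3 ± 10.5 against 80.6 ± 16.1 (−1.55 ± 0.207, 0.000109). Drought genes were lower as a list (camera adjusted p = 0.00101, and adjusted p = 0.423 with an estimated correlation), with SALT (−2.78, adjusted p = 0.0063) and the phosphatase PP2C30 (−2.32, 0.0443) past the threshold and 4 over the list alone. SALT stood at 17.2 ± 3.25 CPM, against 12.2 ± 6.46 in Niyan Wee and 1150 ± 379 in Moddai Karuppan. The PP2C30 call ended without any of 15 libraries (0.171 without Sarali replicate 4), with the ribosomal share as a covariate (0.256), on thinned counts (0.0547) and without Bala replicates 3 and 4 (0.0691). The beta-glucosidase BGLU1 was higher (1.66, adjusted p = 0.0389, 0.0685 with the replicate block) and the anthranilate synthase subunit ASB1 lower (−1.16, 0.0489), calls that ended without any of 12 libraries (0.125 without Sarali replicate 3) and any of 13 (0.168 without Sarali replicate 1), and, single pools aside, under 4 and 7 other alternatives (0.137 and 0.189 with the ribosomal share as a covariate). NBP was higher (0.56, adjusted p = 0.00956), ending only without Sarali replicate 3 (0.0526) among the libraries left out in turn. The number of genes that differed was 265 without Niyan Wee replicates 2 and 3 and Sarali replicate 3, and there BGLU1 (0.334), PP2C30 (0.092) and ASB1 (0.0516) ended.

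Aquaporins as a list were lower in Niyan Wee (camera adjusted p = 0.0161) and higher in Sarali (0.0241) relative to the other two, with adjusted p = 0.849 with an estimated correlation for both, and fry passed neither (0.24 and 0.406). With the 2 matched by name both had adjusted p = 0.015 (0.804 with an estimated correlation). The Niyan Wee libraries lay far apart, with median aquaporin deviations of −0.579 in replicate 2, −0.41 in replicate 3, −0.0658 in replicate 1 and 1.05 in replicate 4. The Niyan Wee call ended without Niyan Wee replicate 2 (0.265) or 3 (0.0709) or Sarali replicate 2 (0.057), and without Niyan Wee replicates 2 and 3 it was 0.984. The Sarali call ended without Niyan Wee replicate 2 (0.145) or 3 (0.0618), Sarali replicate 1 (0.197) or 2 (0.184) or Moddai Karuppan replicate 3 (0.0517), so neither is taken as a difference between the cultivars. By edgeR 0 of 19 passed in Niyan Wee, Sarali or Moddai Karuppan, with 2, 1 and 1 at an unadjusted p below 0.05 and 0 by DESeq2. In the remaining lists and Sri Lankan cultivars 0 genes passed by edgeR. At an unadjusted p below 0.05 up to 7 members of a list passed there, and by DESeq2 up to 4, in both instances expansins in Niyan Wee. Adjusted over the list alone, 3 expansins and 2 root development genes rose and 1 of each fell in Niyan Wee, 2 further drought genes and 1 low oxygen gene rose there, and 1 heat shock protein fell in Sarali. The median, mean and test of a list differed in sign for nutrient uptake, the Casparian strip family and heat shock proteins in Azucena, low oxygen against Bala, aquaporins in Moddai Karuppan, heat shock proteins in Niyan Wee and ribosomal proteins in Sarali, and none of these tests passed. Of the 50 list tests 9 passed with the preset correlation, 0 with camera's estimated correlation (4 at an unadjusted p below 0.05) and 6 with fry, and 10 with the replicate block, the addition being expansins in Niyan Wee (adjusted p = 0.0372 against 0.0625).

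Between pairs, Azucena differed from Moddai Karuppan in 4251 genes, from Sarali in 3826, from Niyan Wee in 2965 and from Bala in 2904. Bala differed from Moddai Karuppan in 3217 genes, from Sarali in 2431 and from Niyan Wee in 2362. Within the Sri Lankan cultivars the counts were 611 for Niyan Wee against Sarali, 503 for Moddai Karuppan against Niyan Wee and 372 for Moddai Karuppan against Sarali. Whether chance could give these Sri Lankan counts was not settled by other splits of the libraries. With the ribosomal share as a covariate the counts were 1543 for Bala against Moddai Karuppan, 889 for Bala against Niyan Wee and 383 for Niyan Wee against Sarali, and the first was 1918 without Bala replicate 4 and 1951 without Moddai Karuppan replicate 1. Without Niyan Wee replicates 2 and 3 and Sarali replicate 3 the counts were 1505 for Bala against Niyan Wee, 275 for Moddai Karuppan against Niyan Wee and 290 for Niyan Wee against Sarali.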

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

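The tests of a shared replicate number, with its label for each number, of low expression, and the cell division relation without number 1 or with 2 more aquaporins were chosen only after the results were seen. After values had been seen, the lower bound of an odds ratio was used because the ratio was infinite, an adjusted p was required of the cell division relation and the share among genes above 1 CPM was set aside as undecided, since a minimum in every cultivar can remove 1 direction.

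Of 163 groups of 4 libraries tested, 11 (6.75%) had a library far from the other three by Dixon's test, and chance gives about 1 in 20. In Niyan Wee replicate 4, TIP1-1 stood at 1170 CPM (the others between 119 and 260), TIP2-1 at 295 (56.6 to 62.8) and NIP2-2 at 44.9 (3.21 to 4.73). In Niyan Wee replicate 2, NIP1-3 stood at 1.6 CPM (3.33 to 3.6). In Bala, TIP1-1 stood at 293 CPM in replicate 1 (707 to 790) and TIP1-2 at 13.5 in replicate 2 (42.1 to 44.9). In Moddai Karuppan, PIP2-3 stood at 93 CPM in replicate 2 (63.1 to 67.7) and SIP1-1 at 59.7 in replicate 1 (46.4 to 48). In Azucena, PIP2-2 stood at 53.1 CPM in replicate 2 (66.5 to 69), XB3 at 47.3 in replicate 1 (34.9 to 35.3) and BADH2 at 28.3 in replicate 3 (14.8 to 16.6).

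Aquaporins spread widely within cultivars, with median deviations over the 16 of at least 10 CPM from −0.58 in Niyan Wee replicate 2 to 1.05 in Niyan Wee replicate 4 on the log2 scale. A handling effect shared by replicate number stays open: same-numbered libraries correlated at a mean of 0.0206 (permutation p = 0.355), a mean that decides nothing when single pairs of number 1 ran from −0.394 to 0.501, and over all genes the pairs of number 1 lay between 0.0463 and 0.25. Aquaporin deviations ran against those of 37 cell division genes over the 20 libraries (Pearson r = −0.624, permutation p = 0.0287, 0.0862 adjusted over 3 relations; Spearman rho = −0.573, p = 0.0296; r = −0.556 without the 2 farthest libraries; r = −0.604, p = 0.0363 with 18 aquaporins), so a varying share of dividing root tissue may contribute, and it cannot be told apart from other sources because the adjusted p missed the threshold. Without the 5 libraries of number 1, whose cell division deviations were all below 0 (−0.291 to −0.0063), r was −0.789 (p = 0.0406; rho = −0.611, p = 0.0927; −0.517 without the 2 farthest). The ribosomal RNA share stays open as well (r = 0.307, p = 0.545; rho = 0.238, p = 0.421; −0.00849 without the 2 farthest), and apart from dividing tissue no biological explanation was tested, as the labels give no grouping within a cultivar.

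Bala differed from the Sri Lankan cultivars in many genes and also had the most ribosomal RNA. The median change of the 3793 called genes was 0.89 between libraries of closer share (66.7% in Bala, 57.6% in the others) and 1.30 between libraries of distant share (79.8% and 25.3%). The ratio was 0.686 (0.525 to 0.836 leaving out a library) where the log odds of the shares would give 0.143. It cannot decide, because the genes and their directions were called on these same libraries, which raises both changes. The closer and distant Bala libraries were also those of pools P1 and P2. Slopes on the share within the other 4 cultivars, without Bala, predicted the direction of 54.7% of the genes (52.4 to 59.6 leaving out a library). Noise in slopes from 16 libraries pulls that percentage towards an even split, so the percentage alone cannot decide. The median change that the slopes predicted in the called direction was 0.0246, against 1.15 observed. Where such slopes hold for Bala too, this size argues against carry-over as the whole cause. With the share as a covariate the median change went from 1.15 (median SE 0.272) to 1.07 (0.349) and 1511 genes stayed past the threshold, so calls ended largely because the errors grew. A partial contribution of the share, and a difference between the cultivars themselves, both stay open.

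Genes higher in Azucena outnumbered genes lower in it. There were 71 genes of at least 5 CPM in Azucena and below 0.1 in each other cultivar, none of the opposite kind, against 3 and 10 for Bala (Fisher's exact test, two-sided, p = 1.04e-10, lower 95% bound of an infinite odds ratio 30.6), which is consistent with reads of the indica cultivars being lost on a japonica reference, although genes missing from those cultivars would give the same. Among called genes of at least 1 CPM in every cultivar 51.5% were higher (95% binomial interval 49.5 to 53.4), against 71.9% of the others. Among those with a mean of at least 10 CPM 44.5% were higher (42 to 47.1), against 67.4% below it. In both splits the excess was thus seen only among the weaker genes, and at a mean of at least 10 CPM more genes were lower. Both levels depend mostly on the other cultivars, so the splits can remove genes higher in Azucena more often. They therefore cannot decide whether near-absent or weakly expressed genes alone make the excess. A difference between the cultivars was not tested separately.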

How the results depend on the processing

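The fits without ribosomal RNA genes, with the ribosomal RNA share as a covariate, with the newer quasi-likelihood method, on thinned counts, without 2 libraries, without 3 libraries and with aquaporins matched by name were chosen only after the data were seen. None of 56 named-gene results was reversed under any alternative run, and none of 83 called list members under the 7 alternatives compared for them. This says little, because named genes were chosen for passing without overlap between the libraries of the sides. The list members, too, had been called on the same libraries. Named-gene calls ended for 16 in pool P2 alone, 11 in pool P1 alone, 9 without 3 libraries, 5 with the ribosomal covariate, 3 on thinned counts, 3 without 2 libraries, 2 with the stricter filter, 2 with the replicate block, 1 with RLE factors and 1 without ribosomal RNA genes. All 18 counts stayed within 1.5 times under RLE factors, no filter, the stricter filter, the replicate block, the pool covariate, removal of ribosomal RNA genes, the newer method and thinning, and the legacy fit, being this version's default, moved nothing. The replicate block changed the calls of the F tests of NIP2-1 (adjusted p = 0.0646) and PIP1-2 (0.0231), of PIP2-2 between Azucena and Bala (0.0578), of KRP3 (0.06) and BGLU1 (0.0685), and of expansins in Niyan Wee as a list (0.0372); 70 of 83 called list members kept their calls with it, and it changed no other call of a count, named gene, list test or aquaporin F test. By DESeq2 there were 4 aquaporins, 1552 genes among the 3 Sri Lankan cultivars, 673 for Moddai Karuppan, 1254 for Niyan Wee and 901 for Sarali against the other two, 958 for Moddai Karuppan against Niyan Wee, 641 for Moddai Karuppan against Sarali and 1127 for Niyan Wee against Sarali. With the ribosomal covariate there were 1 aquaporin, 1607 genes for the Sri Lankan mean against Bala, 1543 for Bala against Moddai Karuppan, 889 for Bala against Niyan Wee and 383 for Niyan Wee against Sarali. Without Bala replicates 3 and 4, fewer samples, there were 1 aquaporin, 1484 genes for the Sri Lankan mean against Bala, 1866 for Azucena, 1234 for Moddai Karuppan, 1131 for Niyan Wee and 1320 for Sarali against Bala. Without Niyan Wee replicates 2 and 3 and Sarali replicate 3, again fewer samples, there were 500 genes among the 3 Sri Lankan cultivars, 289 for Niyan Wee and 265 for Sarali against the other two, 1505 for Bala against Niyan Wee, 275 for Moddai Karuppan against Niyan Wee and 290 for Niyan Wee against Sarali; PIP2-2 passed the F test (0.0412). With PIP2-5 and NIP3-1 matched by name there were 3 aquaporins. On the 8 libraries of a pair there were 1921 genes for Azucena against Bala, 1368 for Bala against Niyan Wee and 365 for Niyan Wee against Sarali. In pool P1 alone, again fewer samples, there were 2498 genes and 0 aquaporins by edgeR (7 at an unadjusted p below 0.05) among the 5 cultivars, 522 among the 3 Sri Lankan ones, 2376 for Azucena against the others, 1126 for the Sri Lankan mean against Bala, 370 for Niyan Wee and 274 for Sarali against the other two; Azucena gave 1349 against Bala, 2101 against Moddai Karuppan, 1807 against Niyan Wee and 1889 against Sarali, Bala gave 798, 831 and 806 against those 3, and Niyan Wee against Sarali 269. In pool P2 alone the values in that order were 2437, 0 (5 at an unadjusted p below 0.05), 299, 1931, 2472, 232 and 171, with 167 for Moddai Karuppan, 1100, 1524, 1244 and 1446 for Azucena, 1455, 1178 and 1211 for Bala, 180 for Moddai Karuppan against Niyan Wee, 114 for Moddai Karuppan against Sarali and 227 for Niyan Wee against Sarali. Of the list tests 0 passed with camera's estimated correlation (4 at an unadjusted p below 0.05, 6 with fry). Leaving out 1 library gave 1 (Moddai Karuppan replicate 1, 3 or 4, Bala replicate 1 or 4) to 8 aquaporins (Niyan Wee replicate 4), 2332 (Bala replicate 4) to 4329 genes (Bala replicate 2) for the Sri Lankan mean against Bala, 371 (Niyan Wee replicate 3) to 800 (Azucena replicate 3) for Niyan Wee, and 1918 (Bala replicate 4; 1951 without Moddai Karuppan replicate 1) to 3849 (Bala replicate 2) for Bala against Moddai Karuppan. Where no reason is given, the cause was not tested. Bala replicate 4 held the fewest non-ribosomal counts (3813615), but thinning every library to that total kept all 18 counts within 1.5 times, so depth alone was not shown to limit them.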

Other observations

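The families grouped by gene name, and the test of neighbouring genes were chosen only after the counts of changed genes had been seen. Several MADS-box transcription factors were lower in Azucena than in the mean of the 4 others. Of 15 measured, MADS57 (log2 fold change −2.04, edgeR adjusted p = 2.03e-05), MADS2 (−1.12, 0.0019), MADS55 (−0.82, 0.0198) and MADS50 (−0.53, 0.00961) were lower and MADS23 was higher (1.46, 0.000656), without any single library too. MADS56 (−2.88, 0.0176; −2.29 without Bala replicate 3 and −7.16 without Azucena replicate 3) and MADS16 (−1.31, 0.0223) also passed, but were low in Bala as well (0.433 and 11.9 CPM, against 0.965 and 15.9 in Azucena). MADS56 ended without Bala replicate 3 (0.181) or Azucena replicate 1 (0.0544) or 4 (0.0556), and MADS16 without Azucena replicate 1 (0.0701), 3 (0.0716) or 4 (0.0574). The beta-glucosidases BGLU26 (−2.07, 0.000609), BGLU30 (−2.03, 0.00467) and BGLU9 (−1.11, 0.000127) were lower in Azucena among 22 measured, as was BGLU20 (−0.52, 0.0292), which ended without Azucena replicate 1 (0.0951), 3 (0.0948) or 4 (0.0572).

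Autophagy genes APG8D (2.79, adjusted p = 0.00367), APG5 (0.84, 0.00438) and APG12 (0.67, 0.00235) were higher in the Sri Lankan mean than in Bala, beside 31.3 points more ribosomal RNA in Bala. APG8C (0.41, 0.0271) and the cellulose synthases CesA2 (0.74, 0.0162) and CesA5 (0.66, 0.0142) were higher too, but APG8C ended without Bala replicate 3 (0.0948) or 4 (0.132), CesA2 without Bala replicate 1 (0.065) or 4 (0.0763) and CesA5 without Bala replicate 3 (0.061) or 4 (0.0571). The kinase CIPK15 stood at 15.1 CPM in Bala and at 1.28, 0.626 and 3.5 in Moddai Karuppan, Niyan Wee and Sarali (−3.41, adjusted p = 0.00322; −2.57 without Bala replicate 4). SDH3-2, SDH7 and SDH8A were lower in the Sri Lankan mean (−1.24, −0.86 and −0.53, adjusted p = 1.47e-07, 0.00176 and 0.00141). Of 106 camera tests of 53 families in these 2 comparisons 3 passed, all of expansins, and none with an estimated correlation. The MADS-box family in Azucena had an adjusted p of 0.193 (adjusted p = 0.556 with an estimated correlation) and the autophagy family against Bala 0.156 (0.924).

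Of the 71 genes near 0 outside Azucena, 68 had a place in the gene order, and 15 of these had another within 5 gene places, against a median of 2 and a highest of 17 in 10000 random sets of 68 genes (permutation test, p = 2e-04). Such grouping may reflect stretches of the genome that differ between Azucena and the indica cultivars, a hypothesis from the same data. LOC112939717 stood at 9.7 CPM in Azucena and at 0 in each of the other cultivars.

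Other splits of the libraries were compared with the real one, 100 per set with the real one included. They were drawn without regard to replicate number or pool, which the real split balances. Among the 5 cultivars the real split was the only 1 of 100 with as many genes in each comparison: 6032 against a highest other of 22 for the F test, 4277 against 129 for Azucena, 2904 against 2, 4251 against 0, 2965 against 30 and 3826 against 935 for Azucena against Bala, Moddai Karuppan, Niyan Wee and Sarali, 3217 against 1, 2362 against 15 and 2431 against 36 for Bala against those 3, 503 against 50, 372 against 1 and 611 against 15 for the Sri Lankan pairs. It was also the only 1 for the Sri Lankan mean against Bala (3816 against 47), the F test among the 3 Sri Lankan cultivars (854 against 359) and Niyan Wee (656 against 604). For Moddai Karuppan 3 splits (432 against a highest of 899) and for Sarali 3 splits (483 against 631) gave as many, the real one included. Each share is under 0.05, and adjusted over the 17 comparisons the shares were 0.0113 where the real split stood alone and 0.03 for the other two. The smallest share that 100 splits can give is 0.01, which is 0.17 when multiplied by the comparisons. By the adjusted share chance can be excluded for the F tests, which ask whether any of their cultivars differ. For the comparisons of Azucena, of Bala and of all pairs, the other groups mixed libraries of several cultivars. Differences between those cultivars then widened the spread within groups, which keeps the counts of other splits low. These splits therefore cannot decide on chance for each of these comparisons. Splits of the Sri Lankan libraries alone gave up to 899 genes, so chance is not excluded for the Sri Lankan pairs. For Moddai Karuppan and Sarali other splits gave more genes than the real one, for Niyan Wee 604 is close to 656 and the count was 371 without Niyan Wee replicate 3, and no more is claimed for these cultivars. The split with 899 genes called over 1.5 times the real count. It and those with 631 and 604 genes put Niyan Wee replicates 2 and 3 and Sarali replicate 3 together, which points to a structure among the libraries beside cultivar. Relabelled copies of a split were counted once after a first run had counted them separately.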
